A study of Homo sapiens with 9 samples.

How the data were processed

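RNA was sequenced from 9 libraries that the labels assign to the HepG2 line, a human line derived from a liver tumour. According to the labels and the protocol text, 3 libraries came from control cells carrying an empty lentiviral vector, 3 from a line overexpressing NFE2L1 and 3 from a line overexpressing NFE2L1DC. NFE2L1 is a transcription factor of the cap'n'collar family that is anchored in the endoplasmic reticulum and, once processed, activates proteasome genes. The protocol writes the other form with a delta sign before the C, the usual notation for a deletion at the C-terminus, and the extent of the deletion is not given in the sources used here. Cells were grown in high-glucose medium with fetal bovine serum and lysed in Trizol, and a sequencing company prepared and sequenced the libraries.

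The deposited table holds TPM values for 58174 genes in 9 columns, 1 per library. TPM is a transcript abundance normalised for length and scaled by the authors within each library, so that a large change in a few abundant genes shifts the values of all others. Each column summed to between 999983.0 and 999991.7, the values were not whole numbers, and no read counts were present. The sequencing depth behind each value is therefore unknown, and no counting interval or detection floor can be given. The processing notes name only the CASAVA software and the GRCh38 genome build. The aligner, the quantifier, the annotation release, the strandedness of the libraries and any filters are not given in the sources used here. Of the listed gene identifiers, 57836 matched GENCODE release 29, which supplied coordinates, biotypes, GC content and transcript lengths.

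A test on counts had been planned for the case that the table held counts. Because it holds TPM, the fallback written before the data were examined was used, limma-trend on log2(TPM + 1). Genes were kept if they reached 1 TPM in at least 3 of the 9 libraries, which left 14118. A gene near 0 elsewhere could thus enter through the libraries of a single group. For lists with many such genes, the counts of members higher in that group are to be read with this limit. A linear model with 1 mean per group was fitted to all 9 libraries in limma 3.58.1 under R 4.3.3, with moderated variances following the trend with abundance (3.34 prior degrees of freedom), and the 3 contrasts between groups were tested 2-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within each contrast, and genes at an adjusted p under 0.05 are described as changed. All log2 fold changes are on the log2(TPM + 1) scale, which understates changes of genes near or under 1 TPM; folds are ratios of mean TPM. Errors of TPM means are standard deviations over 3 libraries, and errors of log2 fold changes are standard errors from the fit. The labels do not say whether the replicates of a group were separate cultures, so p-values measure only the spread between these samples. Each overexpressing line was compared with the same 3 control libraries.

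In simulated data with this number of libraries and genes, the procedure called 86.6% of genes with a simulated absolute log2 change of 1 in NFE2L1 against control, 91% in NFE2L1DC against control and 88.1% in NFE2L1 against NFE2L1DC. At a simulated change of 0.5 it called 31.3%, 38.8% and 38.8%. The unchanged genes among the calls made up 2.04%, 6.21% and 7.98%. Changes were put only into genes whose mean log2(TPM + 1) exceeded the log2 of 10, and noise was drawn independently for each gene. The rates therefore do not cover genes near 1 TPM, or variation that many genes share between the real libraries.

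Before the data were examined, 42 gene lists with 917 symbols were fixed: the proteasome, targets of cap'n'collar factors, stress responses, metabolism, liver functions, signalling, interferon and inflammatory genes, markers of other cell types and RNAs sensitive to library preparation. All symbols were found in the table. For the 37 lists with at least 5 tested members, camera in limma compared the list with all other tested genes at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with a correlation estimated from the data and fry were run as alternatives. For each list the members changed were counted with adjustment over all genes, and again adjusted over the list alone. Neither count allows for correlation between members.

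Genes named singly were taken by a rule fixed before the data were examined. It took NFE2L1, NFE2L2 and NFE2L3; in each contrast the 5 highest and 5 lowest log2 fold changes and the 5 smallest p-values among changed protein-coding genes with a symbol and at least 10 TPM; up to 4 changed members of each list with a camera adjusted p under 0.05 or at least 25% of members changed; and the 5 strongest changes in each direction shared by both lines. For the extremes, the smallest p-values and the shared changes, the libraries of the groups compared also had to be without overlap. Such genes are cleanly separated ones rather than the plain extremes. The rule gave 121 genes. A result for 1 of them is not reported here, and the gene stays in all tests and counts. Any other gene named is stated to have been chosen after its values were seen. Of the 121 genes, 42 overlap another gene present at 1 TPM or more, 21 of them on the same strand and 30 on the opposite strand, and without knowledge of the strandedness reads can be counted for the wrong member of such a pair. Reads shared between close relatives, as among the OAS, IFIT and HLA genes, can also be assigned to the wrong gene.

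Settings varied as planned before the data were examined were no filter and a stricter filter on low values, a pseudocount of 0.1, the replicate number as a block, adjusted p under 0.01, an added minimum absolute log2 fold change of 1, fits to only the 6 libraries compared, and leaving out each library in turn. Settings chosen after seeing the data were median-of-ratios scaling and upper-quartile scaling of the TPM columns, a correction of each library for GC content and transcript length by splines with 5 degrees of freedom, control replicate 3 as the only control, and gene lists without control replicate 3. Median-of-ratios scaling moved the median log2 fold change of all tested genes from 0.17 to 0.01 in NFE2L1 against control, from 0.12 to 0.02 in NFE2L1DC against control and from 0.06 to 0.00 in NFE2L1 against NFE2L1DC, so small changes against control are to be read against those medians. No library was left out of the tests reported. Figures were drawn with matplotlib from the same values.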

Results

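The data are TPM values from 9 RNA-seq libraries labelled HepG2, 3 from vector control cells, 3 from the NFE2L1-overexpressing line and 3 from the line overexpressing the NFE2L1DC form. The series title names the question: an activity of NFE2L1 other than transcription, addressed by setting the transcriptome of the full form beside that of a form written as lacking the C-terminus. Between 21809 and 23396 genes were above 0 in a library, and between 13057 and 13950 reached 1 TPM. The 10 most abundant genes took 13.21% to 15.62% of the TPM, and mitochondrially encoded genes took 15.27% to 18.92%. Depth is unknown because the table holds no counts.

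On the first principal component of log2(TPM + 1), which carried 41.9% of the variance, control replicates 1 and 2 both lay at -43.8, control replicate 3 at 5 and the NFE2L1 libraries between 19.7 and 23. NFE2L1DC replicate 1 lay at 19.2, with replicates 2 and 3 at -1.2 and 0.6. On the second component control replicate 3 lay at -37.9, apart from all other libraries, which lay between -3.6 and 10.9. The deviation of control replicate 3 from control replicates 1 and 2 ran against the GC content of the genes, with a Spearman's rho of -0.68 across 11445 protein-coding genes, which are not independent replicates. The change of NFE2L1 against control had a rho of -0.446 with GC content, that of NFE2L1DC against control -0.374, and that of NFE2L1 against NFE2L1DC -0.246. Against control replicate 3 alone the sign turned, with a rho of 0.162 for NFE2L1 and 0.307 for NFE2L1DC, so the trend against control rests on control replicates 1 and 2. The comparison of the overexpressing lines with each other uses the control libraries only for the estimate of spread.

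**Figure D1:**
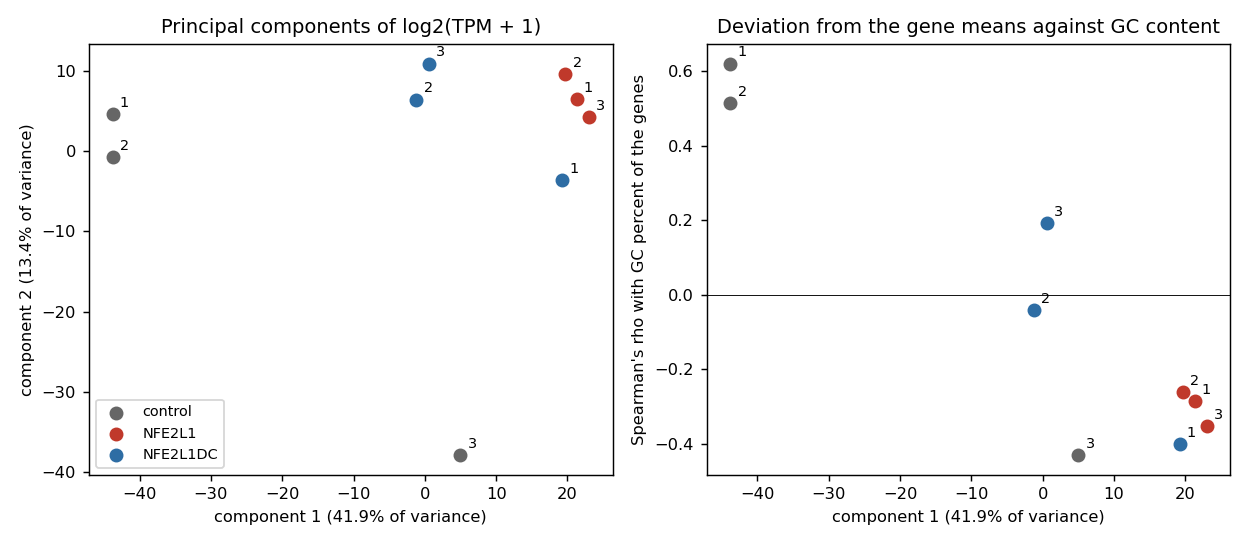
The left panel plots the 9 libraries on the first and second principal components of log2(TPM + 1), with 41.9% and 13.4% of the variance; numbers are replicates. The right panel plots, against the first component, Spearman's rho between the GC percent of genes and the deviation of each library from the gene means, from 0.62 in control replicate 1 to -0.43 in control replicate 3.

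NFE2L1 (ENSG00000082641, GRCh38 chromosome 17, 48048329 to 48061487, plus strand) was higher in both overexpressing lines. Its mean was 83.3 ± 20.2 TPM in control (SD, n = 3), 247 ± 93.5 TPM in the NFE2L1 line and 448 ± 22.9 TPM in the NFE2L1DC line. The log2 fold change against control was 1.52 (SE 0.24, limma adjusted p = 0.00582) with NFE2L1 and 2.44 (SE 0.24, adjusted p = 0.0014) with NFE2L1DC. The NFE2L1 line was lower than the NFE2L1DC line by a log2 fold change of -0.92, which did not pass the test over all genes (adjusted p = 0.228), although the highest NFE2L1 library, at 354.3 TPM, lay under the lowest NFE2L1DC library, at 426.7 TPM. The difference passed only in the fit without NFE2L1 replicate 3, at -1.21 (adjusted p = 0.0382). In all other settings the limma adjusted p lay between 0.137 and 0.597. Gene-level TPM cannot separate the transgene from the endogenous gene. The related factors did not pass the test in any comparison: NFE2L2 was at 20.8 ± 13.7, 20.6 ± 5.7 and 15.1 ± 1.7 TPM in control, NFE2L1 and NFE2L1DC, and NFE2L3 at 1.58 ± 0.791, 3.3 ± 0.488 and 2.91 ± 1.11 TPM.

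**Figure D2:**
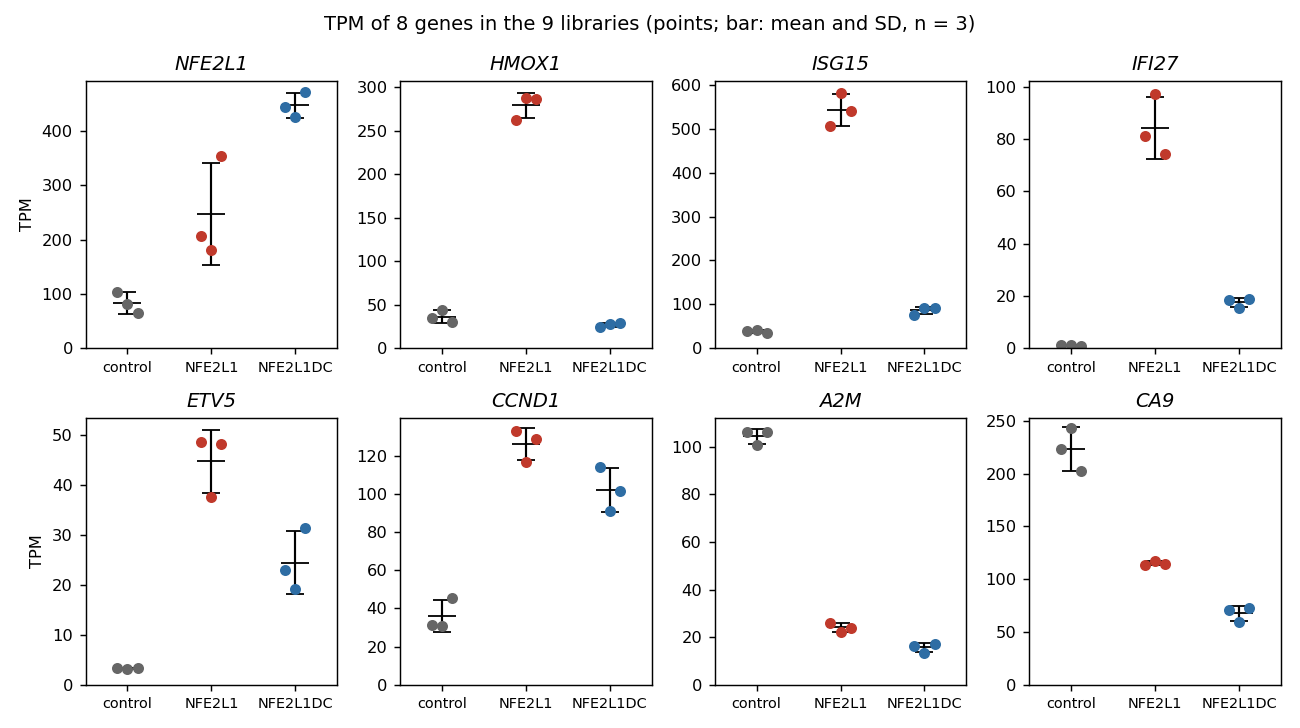
Each panel plots the TPM of 1 gene in the 9 libraries by group, with points for libraries and a bar for the mean and SD of 3 libraries; each axis starts at 0. HMOX1 and ISG15 are highest in the NFE2L1 libraries, while A2M falls from a mean of 104 TPM in control to 24.2 TPM with NFE2L1 and 15.7 TPM with NFE2L1DC.

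The NFE2L1 line was first compared with control, which asks how the transcriptome differs in cells with more of the full form. Interferon-stimulated genes had the highest median change of the 37 lists tested. IFI27 (chromosome 14, 94104836 to 94116698) went from 1.15 ± 0.204 to 84.3 ± 11.9 TPM, a fold of 73.5 and a log2 fold change of 5.31 (SE 0.14, adjusted p = 1.91e-07). IFI6 went from 47.0 ± 13.3 to 669 ± 24.2 TPM. ISG15, a ubiquitin-like protein induced by interferon (chromosome 1, 1001138 to 1014540), went from 37.9 ± 4.03 to 543 ± 37.2 TPM. HMOX1, the heme-degrading enzyme heme oxygenase 1 (ENSG00000100292, chromosome 22, 35380361 to 35394214), went from 36.2 ± 7.06 to 279 ± 14.6 TPM, a fold of 7.7 (log2 fold change 2.93, SE 0.14, adjusted p = 5.53e-06). Of the 35 interferon-stimulated genes tested, 33 rose and none fell, and 34 rose when adjusted over the list alone. The median log2 fold change of the list was 1.68 (camera adjusted p = 1.78e-31, and adjusted p = 0.00168 with an estimated correlation). The oligoadenylate synthetases OAS1 (9.08 ± 1.55 to 92.8 ± 8.76 TPM) and OAS3 (11.1 ± 1.17 to 65.0 ± 4.25 TPM) were among them, as was OAS2, which rose from 0.0217 ± 0.0246 to 9.28 ± 0.638 TPM. Of 10 genes of class I antigen presentation, 7 rose and none fell (8 adjusted over the list alone), with a median of 0.83 (adjusted p = 5.34e-05, and adjusted p = 0.141 with an estimated correlation). HLA-B rose from 213 ± 31 to 565 ± 65.7 TPM and HLA-C from 152 ± 11.1 to 278 ± 16.5 TPM. Of 7 immunoproteasome genes and activators, 4 rose and none fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.0104, and adjusted p = 0.218 with an estimated correlation). The subunit PSMB9 rose by 1.27 and PSMB8 by 0.80 on the log2 scale.

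The list named immediate early genes formed the next group. Its largest changes among called members were in DUSP6, SPRY4, SPRY2 and FOSL1, which are not all immediate early genes in the strict sense. Of 23 immediate early genes tested, 15 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 7.6e-09, and adjusted p = 0.0151 with an estimated correlation). Outside this list, ETV5, an ETS transcription factor (chromosome 3, 186046308 to 186110318), rose from 3.32 ± 0.0907 to 44.8 ± 6.31 TPM (log2 fold change 3.40, SE 0.18, adjusted p = 1.18e-05). ETV4 of the same family rose from 8.65 ± 1.47 to 63.0 ± 4.79 TPM. DUSP4, a phosphatase that inactivates MAP kinases, rose from 0.854 ± 0.198 to 15.9 ± 0.642 TPM. Within the list, the Sprouty gene SPRY2 rose from 2.83 ± 0.677 to 14.1 ± 0.983 TPM and FOSL1 from 17.4 ± 1.56 to 69.4 ± 2.23 TPM. CCND1, which encodes cyclin D1 and is in the list of Wnt targets, rose from 35.9 ± 8.41 to 126 ± 8.36 TPM. Of 21 targets of YAP, TGF-beta and SRF, 8 rose and none fell, and 10 rose and 1 fell when adjusted over the list alone (median 0.48, camera adjusted p = 0.00579, and adjusted p = 0.218 with an estimated correlation). CYR61 rose by 1.14 and CTGF by 1.23 on the log2 scale. Of 12 inflammatory genes of the NF-kB list, 6 rose and none fell (7 adjusted over the list alone; median 0.60, adjusted p = 0.00158, and adjusted p = 0.122 with an estimated correlation). The chemokine CXCL2 rose from 0.999 ± 0.516 to 7.39 ± 1.56 TPM and ICAM1 from 4.13 ± 0.608 to 10.4 ± 1.14 TPM.

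Proteasome subunits were shifted upward as a group by a smaller amount. All 33 had a positive log2 fold change, between 0.03 and 1.07, with a median of 0.34 beside a median of 0.17 over all genes. Of the 33, 10 rose and none fell, and 17 rose when adjusted over the list alone (camera adjusted p = 6.62e-05, and adjusted p = 0.141 with an estimated correlation). After the correction for GC content and length 18 rose and the median was 0.30, while under median-of-ratios scaling 5 rose and the median was 0.15, beside 0.01 over all genes. PSMA3 rose from 37.2 ± 8.47 to 62.0 ± 3.36 TPM, PSMD1 from 30.4 ± 12.1 to 62.1 ± 3.81 TPM and the assembly factor POMP from 58.7 ± 10.3 to 97.7 ± 4.66 TPM. POMP was the only 1 of the 18 assembly and NFE2L1-processing genes that rose, also when adjusted over the list alone (camera adjusted p = 0.0403, and adjusted p = 0.372 with an estimated correlation). The call of this list was lost with the replicate block (camera adjusted p = 0.0537) and after the correction for GC content and length (0.0949). Among 22 genes of the ATF4 and amino-acid starvation list, 7 rose and none fell (11 rose when adjusted over the list alone) (median 0.34, camera adjusted p = 0.000772, and adjusted p = 0.141 with an estimated correlation). The pseudokinase gene TRIB3 rose from 49.4 ± 4.85 to 114 ± 5.5 TPM, and PSAT1 of serine synthesis from 145 ± 39.5 to 281 ± 29 TPM. Of 20 heat shock genes, 7 rose and none fell, and 14 rose and 2 fell when adjusted over the list alone (median 0.37, adjusted p = 0.00579, and adjusted p = 0.257 with an estimated correlation). HSPA8 rose by 0.62 on the log2 scale. Of 17 genes of iron handling, 4 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0161, and adjusted p = 0.141 with an estimated correlation), among them the transferrin receptor TFRC, from 107 ± 58.3 to 238 ± 10.6 TPM. The 31 antioxidant response element genes went both ways, with 8 higher and 4 lower (11 and 5 adjusted over the list alone; camera adjusted p = 0.86). Their median of 0.14 became -0.05 under median-of-ratios scaling, while that of all genes went from 0.17 to 0.01. After the correction for GC content and length 13 were higher and 2 lower, with a median of 0.21 beside 0.17 over all genes. Besides HMOX1 the export pump ABCC3 (13.6 ± 2.13 to 33.2 ± 4.7 TPM) rose.

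Fewer genes fell. A2M, a protease inhibitor of plasma (ENSG00000175899, chromosome 12, 9067664 to 9116229), fell from 104 ± 3.07 to 24.2 ± 1.91 TPM (log2 fold change -2.07, SE 0.11, adjusted p = 1.18e-05), PTGS1 from 17.4 ± 0.535 to 5.2 ± 0.253 TPM and OLFML2A from 64.7 ± 2.59 to 23.0 ± 2.28 TPM. Of 22 genes of glycolysis and gluconeogenesis, 5 fell and none rose (7 adjusted over the list alone; median -0.13, camera adjusted p = 0.000359, and adjusted p = 0.249 with an estimated correlation). The median of this list was 0.01 after the correction for GC content and length, beside 0.17 over all genes. The list was still called lower after it (camera adjusted p = 0.00596). Under median-of-ratios scaling the median of the list was -0.31, beside 0.01 over all genes. ALDOC fell from 93.5 ± 7 to 43.0 ± 2.68 TPM and PFKFB4 from 17.8 ± 4.15 to 5.68 ± 1.08 TPM. Of 19 hypoxia-responsive genes, 3 fell and none rose, the same numbers when adjusted over the list alone (median -0.17, adjusted p = 0.0104, and adjusted p = 0.218 with an estimated correlation). CA9, a carbonic anhydrase induced by low oxygen (chromosome 9, 35673856 to 35681159), fell from 223 ± 20.5 to 115 ± 1.89 TPM and NDRG1 from 255 ± 82.9 to 126 ± 19.2 TPM. Of 54 cytosolic ribosomal protein genes, 9 fell and none rose (17 adjusted over the list alone; median -0.18, adjusted p = 9.52e-12, and adjusted p = 0.141 with an estimated correlation). Their median was -0.03 after the correction for GC content and length, beside 0.17 over all genes, and the list was still called lower. Under median-of-ratios scaling their median was -0.37, beside 0.01 over all genes. Of the 13 mitochondrially encoded genes, 4 fell and none rose (5 adjusted over the list alone; median -0.17, adjusted p = 1.15e-08, and adjusted p = 0.218 with an estimated correlation). Of the 18 p53 target genes, 2 rose and 5 fell (2 and 6 adjusted over the list alone). Camera placed the list lower (adjusted p = 0.0177, and adjusted p = 0.141 with an estimated correlation), with a mean of -0.08 but a median of 0.01. This median became -0.14 under median-of-ratios scaling, beside 0.01 over all genes. CDKN1A, an inhibitor of cyclin-dependent kinases, fell from 201 ± 20.4 to 106 ± 3.38 TPM and BTG2 from 29.2 ± 1.48 to 14.9 ± 0.843 TPM.

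In all, 1468 of 14118 genes changed in the NFE2L1 line against control, 1105 higher and 363 lower, and 288 of them by an absolute log2 fold change of at least 1 (247 higher, 41 lower). After the correction for GC content and length 1536 were higher and 266 lower. Under median-of-ratios scaling, which removes most of the shift in the median of all genes, 542 were higher and 526 lower. Counted anew under this scaling, the lists had 30 interferon-stimulated, 13 immediate early, 5 antigen presentation, 1 immunoproteasome, 6 YAP, 4 inflammatory, 6 ATF4, 4 iron and 2 heat shock genes higher. On the lower side they had 4 glycolysis, 5 hypoxia, 5 ribosomal, 3 mitochondrially encoded, 5 p53, 2 YAP, 1 immediate early, 1 iron and 1 heat shock genes. The count rested on single libraries: without control replicates 1, 2 and 3 it was 624, 510 and 5055, and without NFE2L1 replicates 1, 2 and 3 it was 560, 573 and 531. It was 1249, 1270 and 1052 without NFE2L1DC replicates 1, 2 and 3, which enter only through the shared estimate of spread. Of the 1468 genes, 419 (317 higher, 102 lower) kept their call and direction in all 9 fits that left out 1 library. Among the 88 called genes named by the rule, 38 kept the call at an adjusted p under 0.05 in every other fit that tested them, including IFI27, ISG15, OAS1, HMOX1, ETV5, DUSP4, CCND1, TRIB3, PSMB9, A2M, PTGS1, CDKN1A and CA9, but not PSMD1 or PSMA3. TFRC kept its call in 9 of 18 other fits, with log2 fold changes between 0.44 and 1.67, and NDRG1 in 10 of 18, between -1.22 and -0.45. Of the 18 lists called by camera, 11 were called without control replicate 3, and the calls of the immunoproteasome, assembly, ATF4, hypoxia, iron, p53 and YAP lists were lost.

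The NFE2L1DC line was compared with the same control libraries, which asks the question for the form written as lacking the C-terminus. Among the strongest changes were interferon-stimulated genes and the ETS factors ETV5 and ETV4 on the higher side, and A2M, PFKFB4 and CA9 on the lower side. IFI27 rose from 1.15 ± 0.204 to 17.5 ± 1.8 TPM (fold 15.3, log2 fold change 3.11, SE 0.14, adjusted p = 1.74e-05), IFI6 from 47.0 ± 13.3 to 197 ± 2.57 TPM and ISG15 from 37.9 ± 4.03 to 86.0 ± 8.89 TPM. Of the 35 interferon-stimulated genes, 6 rose and none fell, and 14 rose and 1 fell when adjusted over the list alone (median 0.29, camera adjusted p = 0.000236, and adjusted p = 0.144 with an estimated correlation). HMOX1 was at 26.7 ± 2.55 TPM beside 36.2 ± 7.06 TPM in control, a log2 fold change of -0.41 that did not pass the test (adjusted p = 0.127). ETV5 rose from 3.32 ± 0.0907 to 24.5 ± 6.23 TPM (log2 fold change 2.54, SE 0.18, adjusted p = 0.000339), ETV4 from 8.65 ± 1.47 to 34.6 ± 5.33 TPM and CCND1 from 35.9 ± 8.41 to 102 ± 11.5 TPM. Of the 23 immediate early genes, 7 rose and none fell, and 14 rose and 1 fell when adjusted over the list alone (median 0.51, camera adjusted p = 1.35e-06, and adjusted p = 0.0699 with an estimated correlation). SPRY2 rose by 1.37 and IER3 by 1.12 on the log2 scale. Among the 21 targets of YAP, TGF-beta and SRF, 6 rose and none fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.0756), with a rise of 1.23 for CYR61.

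A2M fell from 104 ± 3.07 to 15.7 ± 1.93 TPM (log2 fold change -2.66, SE 0.11, adjusted p = 1.28e-05) and CA9 from 223 ± 20.5 to 67.6 ± 6.99 TPM (log2 fold change -1.71, SE 0.10, adjusted p = 8.15e-05). Of the 19 hypoxia-responsive genes, 4 fell and none rose (10 fell when adjusted over the list alone) (median -0.33, camera adjusted p = 7.74e-08, and adjusted p = 0.0702 with an estimated correlation). NDRG1 fell from 255 ± 82.9 to 82.3 ± 10.1 TPM, and BNIP3 and EGLN3 were the other members. Of 22 genes of glycolysis and gluconeogenesis, 6 fell and none rose (9 adjusted over the list alone; median -0.16, adjusted p = 5.84e-07, and adjusted p = 0.193 with an estimated correlation). PFKFB4 fell by 2.02, ALDOC by 1.04 and PGK1 by 0.49 on the log2 scale. With control replicate 3 as the only control, the camera adjusted p of the glycolysis list was 0.337 here and 0.799 in the NFE2L1 line.

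Proteasome subunits had a positive log2 fold change in 32 of 33 cases, with a median of 0.17 beside 0.12 over all genes. Of the 33, 3 rose and none fell (7 adjusted over the list alone; camera adjusted p = 0.00261, and adjusted p = 0.193 with an estimated correlation). They were PSMA3, PSMD11 and ADRM1, with log2 fold changes of 0.70, 0.39 and 0.33, and the camera adjusted p was 0.0689 without control replicate 3. Of the 22 ATF4 genes, 2 rose, TRIB3 by 0.91 and CEBPB by 0.41, and none fell (10 and 1 adjusted over the list alone; median 0.27, adjusted p = 0.0045, and adjusted p = 0.193 with an estimated correlation). Of the 20 heat shock genes, 2 rose, HSPA1A by 0.45 and STIP1 by 0.34, and none fell (14 and none adjusted over the list alone; median 0.38, adjusted p = 5.97e-05, and adjusted p = 0.193 with an estimated correlation). Of the 31 antioxidant response element genes, 2 rose and none fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.972). Of the p53 target genes 3 fell and none rose, also when adjusted over the list alone, and CDKN1A went from 201 ± 20.4 to 105 ± 6.19 TPM. Camera placed the list lower (adjusted p = 0.0218, and adjusted p = 0.193 with an estimated correlation), with a mean of -0.09 but a median of 0.02. Of the 54 ribosomal protein genes only RPL9 fell (none adjusted over the list alone; median -0.12, adjusted p = 5.84e-07, and adjusted p = 0.283 with an estimated correlation), and the correction for GC content and length ended the call of the list (adjusted p = 0.137). Of the mitochondrially encoded genes only MT-ND3 fell, also when adjusted over the list alone (list median -0.08, adjusted p = 0.000788, and adjusted p = 0.52 with an estimated correlation).

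In all, 509 genes changed in the NFE2L1DC line against control, 291 higher and 218 lower, and 89 of them by an absolute log2 fold change of at least 1 (60 higher, 29 lower). After the correction for GC content and length 508 were higher and 176 lower, and under median-of-ratios scaling 119 were higher and 198 lower. Counted anew under this scaling, the lists had 6 interferon-stimulated, 7 immediate early, 3 YAP, 1 ATF4, 1 inflammatory, 1 proteasome and no heat shock genes higher, with a proteasome median of 0.05 beside 0.02 over all genes. On the lower side they had 6 hypoxia, 4 glycolysis, 3 p53 and no ribosomal or mitochondrially encoded genes. The count was 211, 115 and 3444 without control replicates 1, 2 and 3, and 137, 400 and 119 without NFE2L1DC replicates 1, 2 and 3. It was 269, 267 and 230 without NFE2L1 replicates 1, 2 and 3, which enter only through the shared estimate of spread. Of the 509 genes, 97 (56 higher, 41 lower) kept their call and direction in all 9 fits that left out 1 library. Of the 50 called genes named by the rule, 19 kept the call at an adjusted p under 0.05 in every other fit that tested them, among them IFI27, IFI6, ISG15, ETV5, ETV4, A2M, CA9, TRIB3, ALDOC, CDKN1A, CYR61 and SPRY2. Of 18 other fits, PSMA3 kept its call in 6, PSMD11 in 4, ADRM1 in 3, HSPA1A in 6, STIP1 in 8, RPL9 in 3 and MT-ND3 in 7. Of the 14 lists called, 10 were called without control replicate 3, and the calls of the proteasome, ATF4, p53 and NF-kB lists were lost.

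**Figure D3:**
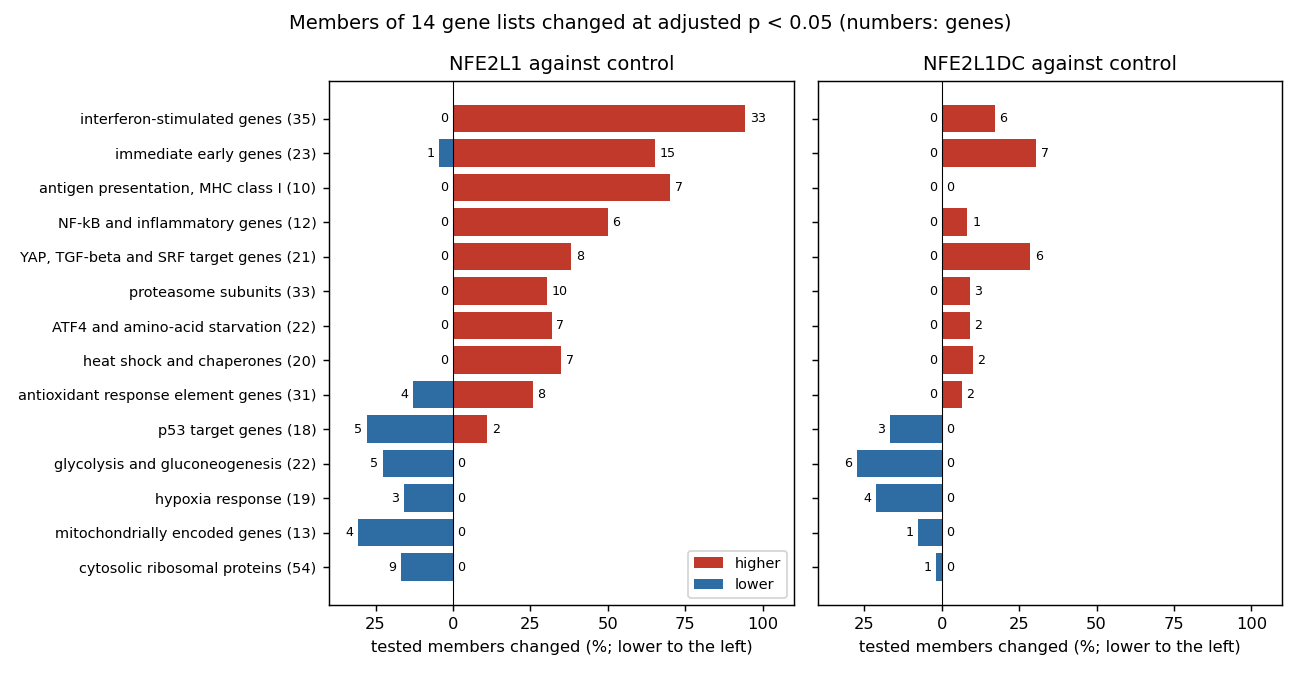
Bars give the percent of tested members of 14 gene lists that rose (right) or fell (left) at an adjusted p under 0.05, for NFE2L1 and NFE2L1DC against control; numbers beside the bars are genes and numbers in brackets are members tested. Of the 35 interferon-stimulated genes, 33 rose with NFE2L1 and 6 with NFE2L1DC. Under median-of-ratios scaling the antioxidant median with NFE2L1 goes from 0.14 to -0.05 and the p53 median from 0.01 to -0.14. The median of all genes goes from 0.17 to 0.01.

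The direct comparison of NFE2L1 with NFE2L1DC tests where the overexpressing lines differ. The labels give 1 line per form, so an effect of the form cannot be told apart from other differences between the lines. HMOX1 was at 279 ± 14.6 TPM with NFE2L1 and at 26.7 ± 2.55 TPM with NFE2L1DC, a fold of 10.4 (log2 fold change 3.34, SE 0.14, adjusted p = 5.79e-06). ISG15 was at 543 ± 37.2 and 86.0 ± 8.89 TPM (fold 6.32, log2 fold change 2.65, SE 0.11, adjusted p = 5.79e-06). IRF7, a transcription factor of the interferon response, was at 29.8 ± 2.93 and 4.31 ± 0.621 TPM, beside 5.01 ± 0.52 TPM in control. UBE2L6, the conjugating enzyme for ISG15, was at 25.3 ± 1.67 and 3.71 ± 0.467 TPM, and IFIT3 at 11.5 ± 1.3 and 1.38 ± 0.308 TPM. All 35 interferon-stimulated genes tested had a higher mean log2 value with NFE2L1, with a median difference of 1.29. Of them 26 were higher and none lower (34 adjusted over the list alone; camera adjusted p = 7.25e-69, and adjusted p = 0.000169 with an estimated correlation).

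Further groups were higher with NFE2L1 than with NFE2L1DC. Of 10 complement and coagulation genes, 3 were higher and none lower (6 adjusted over the list alone; median 0.53, camera adjusted p = 1.16e-06, and adjusted p = 0.0183 with an estimated correlation). C1S was at 38.0 ± 8.05 and 13.0 ± 2.16 TPM, and CFB at 20.9 ± 2.37 and 11.2 ± 0.937 TPM. A2M was the other member, but it fell against control in both lines, and its fall was only smaller with NFE2L1. Its call was kept in 2 of 17 other fits. Of 10 genes of class I antigen presentation 3 were higher, HLA-B, HLA-C and TAP1, and none lower (6 adjusted over the list alone; median 0.48, adjusted p = 8.86e-08, and adjusted p = 0.0564 with an estimated correlation). Of 23 immediate early genes, JUN, PHLDA1 and FOSL1 were higher and none lower (9 adjusted over the list alone; median 0.31, adjusted p = 3e-07, and adjusted p = 0.0183 with an estimated correlation). Of 12 inflammatory genes tested, CXCL2, CXCL3 and IL6 were higher and none lower (4 adjusted over the list alone). The camera adjusted p was 0.00305, and 0.0795 with an estimated correlation. Of the 23 genes listed, 9 stayed under 1 TPM in all libraries. The median of the 23 was 0.49 TPM in control, 1.73 TPM with NFE2L1 and 0.73 TPM with NFE2L1DC. Of 16 other fits, CXCL3 kept its call in 15 and IL6 in 3. Of 19 hypoxia-responsive genes, CA9 was higher with NFE2L1 by 0.77 (SE 0.10, adjusted p = 0.00694) and none was lower. In this list 5 were higher when adjusted over the list alone (median 0.39, camera adjusted p = 6.67e-06, and adjusted p = 0.0727 with an estimated correlation). The fall of CA9 was therefore smaller with NFE2L1, at 115 ± 1.89 TPM, than with NFE2L1DC, at 67.6 ± 6.99 TPM. Of 7 immunoproteasome genes only PSMB9 was higher, by 0.86 (adjusted p = 0.0171), and 5 were higher when adjusted over the list alone (camera adjusted p = 1.32e-05, and adjusted p = 0.0826 with an estimated correlation). None of the 33 proteasome subunits differed singly or when adjusted over the list alone. Their median difference was 0.11, beside 0.06 over all genes (camera adjusted p = 0.0197, and adjusted p = 0.276 with an estimated correlation). Under median-of-ratios scaling it was 0.05, beside 0.00 over all genes.

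Lower with NFE2L1 than with NFE2L1DC were RAB40C (8.39 ± 1.23 and 20.2 ± 2.65 TPM), FN3KRP (23.6 ± 6.57 and 52.4 ± 3.81 TPM), TRIM16 (49.6 ± 3.93 and 106 ± 8.84 TPM), TNNC1 (10.6 ± 1.98 and 21.1 ± 1.58 TPM) and OLFML2A (23.0 ± 2.28 and 35.6 ± 2.97 TPM). HPD, an enzyme of tyrosine breakdown, was at 295 ± 8.24 and 426 ± 26.8 TPM.

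In all, 112 genes differed between the overexpressing lines, 101 higher and 11 lower with NFE2L1. Of them 57 differed by an absolute log2 difference of at least 1 (54 higher, 3 lower). Median-of-ratios scaling gave 70 higher and 6 lower, among them 23 interferon-stimulated, 2 complement, 2 immediate early, 2 inflammatory, 1 antigen presentation and no hypoxia or immunoproteasome genes. Without NFE2L1 replicates 1, 2 and 3 the count was 55, 50 and 49, and without NFE2L1DC replicates 1, 2 and 3 it was 75, 53 and 53. It was 88, 89 and 147 without control replicates 1, 2 and 3. Of the 112 genes, 39 (38 higher, 1 lower) kept their call in all 9 fits that left out 1 library, and 10 of 28 named genes kept it at an adjusted p under 0.05 in every other fit that tested them: HMOX1, ISG15, IRF7, UBE2L6, IFIT3, OAS2, OAS3, C1S, HLA-C and CXCL2.

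Against the shared control, 396 genes changed in the same direction in both lines, 258 higher and 138 lower, and none in opposite directions. Independent lists of these sizes would share 22.8 higher and 5.6 lower genes. Because both lines are set against the same 3 control libraries, chance alone makes the lists overlap: in 100 simulations of unchanged groups with a shared control the mean was 44.9 genes, and 1 of 100 was as large. Few simulations carried that mean, since 95% of them gave between 0 and 11.05 genes. The correlation of the log2 fold changes across genes was 0.758, beside a simulated mean of 0.536 with 95% of simulations between 0.0965 and 0.921, and 24 of 100 were as large. Separate control libraries for each line were not used here. The strongest genes shared by both lines were IFI27, ETV5, IFI6, ETV4 and LRRC8D on the higher side and A2M, PFKFB4, PTGS1, CRABP2 and CLIC3 on the lower side. LRRC8D, a subunit of volume-regulated anion channels, went from 4.91 ± 1.13 TPM in control to 19.8 ± 1.47 TPM with NFE2L1 and 17.5 ± 1.62 TPM with NFE2L1DC, and PTGS1 from 17.4 ± 0.535 to 5.2 ± 0.253 and 5.91 ± 0.355 TPM. WFDC1 went from 88.1 ± 3.03 to 171 ± 8.3 and 173 ± 7.75 TPM. The count of shared genes was 159, 98 and 3036 without control replicates 1, 2 and 3. It was 181, 187 and 163 without NFE2L1 replicates 1, 2 and 3, and 113, 319 and 108 without NFE2L1DC replicates 1, 2 and 3.

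**Figure D4:**
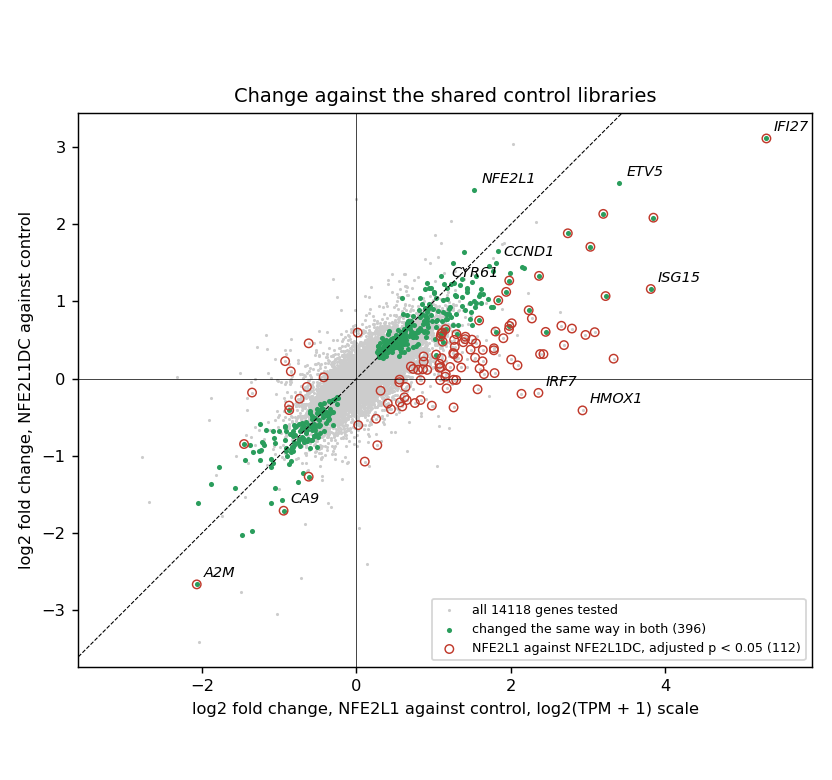
Each point is 1 of 14118 genes, with the log2 fold change of NFE2L1 against control on the horizontal axis and of NFE2L1DC against control on the vertical axis; the dashed line marks equal change. Green points are the 396 genes changed in the same direction in both. Red circles are the 112 genes that differed between the lines, of which 101 lie under the dashed line and were higher with NFE2L1.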

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

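All tests of the patterns below and the regroupings of libraries for the counts of changed genes were chosen only after the results were seen, while the regroupings for the gene lists and for the genes shared by both lines were written before.

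Many genes typical of liver cells were at or near 0 in all 9 libraries, although the labels name a liver-derived line. All genes named in this paragraph except HPD were chosen after their values were seen. ALB, APOB, TTR, SERPINA1, FGB and FOXA2 were at 0 in every library, and AFP and HNF4A did not exceed 0.238 and 0.151 TPM. KRT8, KRT18, CPS1 and HPD, which hepatocytes also make, averaged 1160, 875, 938 and 422 TPM and go the other way. VIM averaged 833 TPM. Of 2711 protein-coding genes with a median of at least 50 TPM, 0.0738% were at 0 in any library. That share cannot judge failed estimates in the table, because a gene at 0 in all libraries cannot have such a median. None of 123 proteasome, ribosomal and complex I genes was at 0 in any library, which argues against failed estimates for those lists only. Cells other than liver-like HepG2 cells cannot be told apart from HepG2 cells that had lost the liver programme, since the count of 24 of 25 listed liver secreted proteins under 1 TPM in all libraries only restates the pattern. The epithelial genes CDH1 and EPCAM were also near 0, with highest values of 0.0569 and 0.0464 TPM. Of 16 listed epithelial genes, 8 stayed under 1 TPM in all libraries. What this means for the identity of the cells was not tested. No other line was tested as a source, and no biological explanation from the groups was tested because all 3 groups share the pattern.

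Control replicate 3 stood apart from control replicates 1 and 2, with a trend in GC content; it lay nearer to the overexpressing libraries on the first principal component and apart from all 8 others on the second component. GC content or transcript length as the whole cause of the calls with NFE2L1 against control is argued against, since 1197 of the 1468 genes changed stayed changed in the same direction after the correction. A mislabelled overexpressing library is argued against by 64 TPM of NFE2L1 in control replicate 3, beside 180.6 TPM in the lowest overexpressing library. A library preparation or RNA quality gradient across groups may be involved: inside the NFE2L1DC group the difference of replicate 1 from replicates 2 and 3 had a rho of -0.404 with GC content, the sign it had inside the control group (-0.68). The labels give no preparation batch, and a true difference between the control cultures was not tested.

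Interferon-stimulated genes and HMOX1 were higher with NFE2L1 than with NFE2L1DC, and GC content or length bias is argued against, since all 26 interferon-stimulated genes called higher stayed called after the correction. More NFE2L1 mRNA in the NFE2L1 line is argued against, since the 95% interval of the log2 difference in NFE2L1 itself, from -1.46 to -0.37, lies wholly on the side of less mRNA, although this difference did not pass over all genes (adjusted p = 0.228). A difference between the lines other than the form of NFE2L1 they carry cannot be told apart from the form, because the labels give 1 line per form; 6 of the interferon-stimulated genes were also higher in the NFE2L1DC line than in control. The form of NFE2L1 stays open as a biological explanation, as does a difference in how the lines were made, such as in the viral preparations, which was not tested; the controls carried an empty vector. Library preparation also stays open, since the RNAs sensitive to it had a median of -0.92 in the same comparison (camera adjusted p = 0.00295, and adjusted p = 0.255 with an estimated correlation).

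The change against control differed between the lines, by the direct test of NFE2L1 against NFE2L1DC, for the named genes that follow, with values as log2 fold change with NFE2L1 minus that with NFE2L1DC. Interferon and antigen presentation genes gave 3.07 for OAS2, 2.65 for ISG15, 2.54 for IRF7, 2.48 for UBE2L6, 2.40 for IFIT3, 2.20 for IFI27, 2.16 for OAS1, 1.84 for OAS3, 1.76 for IFI6, 1.32 for IFI44, 0.89 for HLA-B, 0.86 for PSMB9, 0.74 for HLA-C and 0.68 for TAP1. HMOX1 gave 3.34. Inflammatory and complement genes gave 1.91 for CXCL2, 1.76 for CXCL3, 1.46 for C1S, 0.94 for IL6, 0.84 for CFB, 0.60 for A2M and 0.55 for the macrophage marker CD68. Signalling, transcription factor and matrix genes gave 1.06 for DUSP4, 1.06 for JUN, 0.87 for PHLDA1, 0.85 for ETV4, 0.81 for FOSL1 and 0.51 for FN1. The linker histone gene H1F0 and CA9 each gave 0.77. Negative differences were -0.52 for HPD, -0.61 for OLFML2A, -0.94 for TNNC1, -1.08 for TRIM16, -1.15 for FN3KRP and -1.17 for RAB40C. Several of these calls were fragile: of 17 other fits CD68 kept its call in 1, A2M in 2, FOSL1 in 4, TNNC1 and OLFML2A in 7, and PSMB9 and HPD in 8, and of 16 IL6 kept it in 3 and PHLDA1 in 7. For IFI27, OAS1, IFI6, IFI44, DUSP4, ETV4, H1F0 and FN1 the other fits were not tallied gene by gene in this comparison. These genes entered the count over all 112 genes in the 9 fits that left out 1 library.

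Gene lists differed between the lines by the same comparison, with camera at its preset correlation. Over all tested genes the median difference was 0.06, against which small values are to be read. The median differences were 1.29 for interferon-stimulated genes, 0.53 for complement and coagulation, 0.48 for class I antigen presentation, 0.39 for hypoxia, 0.38 for the immunoproteasome, 0.31 for immediate early genes, 0.28 for inflammatory genes, 0.18 for the unfolded protein response, 0.16 for proteasome assembly, 0.11 for proteasome subunits and 0.11 for ATF4 genes. They were -0.92 for RNAs sensitive to library preparation, -0.10 for mitochondrially encoded genes, -0.09 for amino acid and urea cycle metabolism and -0.05 for ribosomal proteins. Of these 15 lists 3 passed with an estimated correlation, namely interferon-stimulated, immediate early and complement genes.

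Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05, and in each of them 1 split, the real one, gave the highest count of genes. NFE2L1 against control called 1468 genes and at most 2 in another split, NFE2L1DC against control 509 and at most 3, and NFE2L1 against NFE2L1DC 112 and at most 4. For gene lists the real split was likewise 1 of 10, with 18 lists and at most 11 in another split, 14 and at most 9, and 15 and at most 9, so camera at its preset correlation called many lists in splits that mix the groups. Of 100 assignments of the 9 libraries to 3 groups, drawn at random with the real one included, 1 gave as many as 396 genes shared by both lines, the real one. The highest other gave 227 and kept the same 3 control libraries together. Others that kept them together gave 211 and 223, and assignments with any other control group gave at most 50. The share therefore mainly tests whether the controls differ from the rest. Chance around a shared control is not excluded, since few assignments kept the controls together. In the simulations of unchanged groups with a shared control, 1 of 100 was also as large.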

How the results depend on the processing

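Median-of-ratios and upper-quartile scaling, the GC and length correction, control replicate 3 as the only control, and the gene lists without control replicate 3 were chosen after seeing the data. The other settings were planned. Planned settings that need read counts, namely count-based models and scalings, were not run because the table holds TPM. Depth is unknown, so what it limits cannot be stated.

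The counts of changed genes are given in the order NFE2L1 against control (1468), NFE2L1DC against control (509), NFE2L1 against NFE2L1DC (112) and shared by both lines (396). A stricter filter, a pseudocount of 0.1, upper-quartile scaling and the GC and length correction each left all 4 within 1.5 times. With the replicate block they were 872, 198, 58 and 165. The replicate numbers were not used as pairs in the reported fit, since deviations of libraries with the same number correlated between -0.1893 and 0.1086 across genes. At adjusted p under 0.01 they were 400, 104, 47 and 88, and with an absolute log2 fold change of at least 1 they were 288, 89, 57 and 63, as stricter thresholds require. Fits to only the 6 libraries compared gave 848, 101 and 111, with 88 shared, and rest on fewer degrees of freedom. Control replicate 3 as the only control gave 307, 68 and 62 shared, with the lone library assumed to vary like the other groups. Without a filter the first count was 947, and median-of-ratios scaling gave 317 for the second and 251 shared. The cause of these moves was not tested.

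Leaving out 1 library gave 510 to 5055, 115 to 3444, 49 to 147 and 98 to 3036 genes. The highest values all came without control replicate 3, and the lowest without control replicate 2, except in NFE2L1 against NFE2L1DC, where the lowest came without NFE2L1 replicate 3. NFE2L1 itself ranged from -1.21 to -0.72 in NFE2L1 against NFE2L1DC. It passed the test only without NFE2L1 replicate 3, at -1.21 (adjusted p = 0.0382), beside -0.92 (adjusted p = 0.228) with all libraries and adjusted p up to 0.597 in other fits. Its rise against control kept direction and call in every setting run, from 1.23 to 1.87 with NFE2L1 and from 2.27 to 2.79 with NFE2L1DC.

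Of the 18, 14 and 15 gene lists called in the 3 comparisons, camera with an estimated correlation called 2, 0 and 3. They were the interferon-stimulated and immediate early lists against control, and these with complement genes between the overexpressing lines. Fry for changes in either direction called 35, 28 and 17. Fry for changes in 1 direction (21, 13, 10), the replicate block (17, 13, 15) and the GC and length correction (16, 13, 18) stayed within 1.5 times. After the GC and length correction 15, 12 and 14 of the lists called were still called. Control replicate 3 as the only control called 16 and 12 lists against control, and leaving it out called 12 and 10. Of the 18 and 14 lists, 15 and 8 were still called with it alone, with glycolysis, complex I, mitochondrially encoded (adjusted p = 0.196), p53 (0.125), mesenchymal and ribosomal (0.489) genes lost with NFE2L1DC, and 11 and 10 without it. After the GC and length correction the assembly list lost its call in both comparisons that had it, complex I in both, histones with NFE2L1 and ribosomal proteins with NFE2L1DC.

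Of 172 results for named genes, none that passed the test reversed in any fit. NFE2L2, which passed in none, lay between -0.83 and 0.60 with NFE2L1 and between -1.23 and 0.21 with NFE2L1DC. The number that fell short of the threshold was highest with control replicate 3 as the only control (77 of 142), and was 59 without control replicate 2, 50 in fits to 6 libraries, 43 with the replicate block, 34 with median-of-ratios scaling, 14 with the GC and length correction and 7 with a pseudocount of 0.1. Without control replicate 3 none fell short and 2 newly passed, NFE2L3 against control in both lines.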

Other observations

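No hypothesis beyond those above was tested, and the lists described here were fixed before the data were examined. Matrix and cell junction genes went both ways. Of 16 mesenchymal and fibroblast genes, 2 rose and 3 fell with NFE2L1 (the same when adjusted over the list alone; camera adjusted p = 0.128), and 1 rose and 3 fell with NFE2L1DC (2 and 4 adjusted over the list alone; adjusted p = 0.0218, and adjusted p = 0.313 with an estimated correlation). FN1, fibronectin, went from 36.6 ± 2.69 TPM in control (SD, n = 3) to 80.2 ± 1.95 with NFE2L1 and 56.0 ± 5 with NFE2L1DC, and both changes passed the limma test over all genes. The cadherin gene CDH2 rose with NFE2L1, by a log2 fold change of 0.90 (adjusted p = 0.0137). COL3A1, a fibrillar collagen, fell from 107 ± 7.2 to 73.8 ± 3.68 and 69.5 ± 7.18 TPM, and TAGLN fell with NFE2L1DC, from 76.5 ± 10.2 to 45.6 ± 3.62 TPM. Of 8 epithelial genes 1 rose and 1 fell with NFE2L1 (camera adjusted p = 0.144) and 1 fell with NFE2L1DC (adjusted p = 0.353). The claudin gene CLDN7 was the 1 that fell, from 71.0 ± 4.29 to 40.1 ± 2.77 and 46.8 ± 7.89 TPM. Of the fetal liver list, KRT7, a keratin, rose from 536 ± 48.9 to 930 ± 38.6 and 816 ± 60.6 TPM.

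Several lists tied to metabolism and growth did not pass against control in either line, with camera adjusted p for NFE2L1 and NFE2L1DC in that order. Cholesterol synthesis gave 0.293 and 0.505 with 1 and 0 of 24 genes changed, fatty acid synthesis 0.377 and 0.364, fatty acid oxidation 0.372 and 0.511, and autophagy and lysosome genes 0.698 and 0.73. AMPK subunits and kinases gave 0.299 and 0.364, the cell cycle list 0.582 and 0.464 with 1 and 0 of 32 genes changed, and the unfolded protein response 0.945 and 0.0672 with none of 20 genes changed in any comparison. Wnt targets gave 0.86 and 0.946, metallothioneins 0.355 and 0.47, the cap'n'collar, MAF and KEAP1 family 0.769 and 0.863, and amino acid and urea cycle genes 0.172 and 0.863. Hepatocyte transcription factors gave 0.945 and 0.863 with 5 of 19 testable, fetal liver genes 0.768 and 0.964 with 5 of 14, and cancer-testis and imprinted genes 0.582 and 0.505. Complement and coagulation genes had 6 higher and 1 lower of 10 with NFE2L1 (adjusted p = 0.0589) and 1 and 1 with NFE2L1DC (adjusted p = 0.946). The nuclear complex I list had no gene changed among 36, with medians of -0.06 and -0.04 (adjusted p = 0.00158 and 0.0244, and adjusted p = 0.309 and 0.536 with an estimated correlation). In the histone list 1 and 2 of 12 genes fell, and H1F0, 1 of the 2, is a linker histone that does not depend on replication (adjusted p = 0.0183 and 0.000788, and adjusted p = 0.218 and 0.193 with an estimated correlation).

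Most markers of other cell types were near 0. The leukocyte gene PTPRC, chosen after its values were seen, was at 0 in all 9 libraries, and 14 of 17 blood and immune markers, 9 of 12 endothelial markers and 10 of 13 neuronal markers stayed under 1 TPM in all libraries. Of the 3 testable blood and immune markers CD68 rose with NFE2L1, from 22.5 ± 0.469 to 37.4 ± 3.96 TPM, and it is also present in many other cells. Of the 3 testable endothelial markers EGFL7 fell with NFE2L1DC, from 55.4 ± 5.45 to 37.6 ± 1.48 TPM. Of 25 genes of cytochrome P450, conjugation and bile acid metabolism, 23 stayed under 1 TPM, and CYP1A1 rose with NFE2L1 from 3.67 ± 0.542 to 5.96 ± 0.481 TPM, a call kept in 8 of 18 other fits. The 10 RNAs sensitive to library preparation had a median log2 fold change of -0.43 with NFE2L1 (camera adjusted p = 0.0549) and 0.32 with NFE2L1DC (adjusted p = 0.906) against control. The comparison that passed was NFE2L1 against NFE2L1DC, with a median of -0.92 (adjusted p = 0.00295, and adjusted p = 0.255 with an estimated correlation), and none changed singly in any comparison.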
